A study of Mus musculus with 18 samples.

How the data were processed

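RNA from mouse cortical neuronal cultures was sequenced after poly(A) enrichment, in 18 libraries of 3 groups, mSc, Psmb5 and Psmb8, with 6 libraries each, per the labels' protocols and treatment tags. The authors deposited 1 table of raw read counts per Ensembl gene, with 1 column per library and no pooling; its values were whole numbers and its library totals differed. STAR 2.4 and DESeq2 are named in the submitters' processing notes, as are the genome builds GRCm39 and mm10, with no role given. The gene counter, its strand setting, the rule for reads that map to several places and the annotation release are not given in the sources used here. Reads shared between a gene and a close copy or an overlapping or antisense gene could therefore be split in ways that cannot be checked. Gbp2 and its relatives and the beta-tubulins are examples. Which other named genes this concerns was not examined. Whether counts of Psmb5 and Psmb8 come from the transgene or the chromosomal gene cannot be told from gene counts.

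The table held 43629 gene IDs, of which 42462 were given a symbol from a table of Ensembl IDs and 1167 kept their ID. All columns were matched to samples by title. Coordinates, gene length and GC content were taken from GENCODE's annotation of GRCm38 and its genome, so they may differ from the build the counts were made on; 99.3% of the tested genes had a GC value. No pair of libraries within a group looked like a library deposited more than once: over 45 pairs the chi-square of the counts per degree of freedom ranged from 2.80 to 35.3.

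Counts were tested with edgeR 4.0.16 in R 4.3.3: genes with too few counts were removed with filterByExpr by group, leaving 15671, library sizes were scaled with TMM, and the quasi-likelihood test was run on 1 fit of all 18 libraries with group as the factor. P-values were adjusted with Benjamini and Hochberg's method over the genes of a comparison, with a threshold of 0.05. Standard errors of the log2 fold changes of single genes were derived from the quasi-likelihood F statistic. CPM values refer to counts in tested genes after TMM scaling. Of each library's counts, 99.9% lay in tested genes. At totals of 15337511 to 21074229 counts a gene at 1 CPM has about 15 to 21 counts, so counting error limits the low genes.

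The groups share replicate numbers, and the labels do not say what a number means. The design without the number was fixed before the data were examined, with the number as a block as its alternative. The pairing was then checked on deviations of log2 CPM from the group means. All 18 same-numbered pairs between groups correlated positively, with r from 0.45 to 0.73 (mean 0.60), against a mean of -0.12 over 90 differently numbered pairs (range -0.54 to 0.65). In 14 of 18 libraries the highest correlations were with the libraries of their own number. The numbers were therefore taken to pair the samples, and blocked values are given where they change a call or a count by more than 1.5 times. The common biological coefficient of variation was 17.9% without the block and 5.94% with it.

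A total of 27 gene lists (proteasome parts, interferon and inflammation, energy and redox metabolism, stress responses, synapse, and markers of cell types the cultures could hold) were fixed before the data were examined, and 26 had at least 5 tested members. Psmb5 and Psmb8 were left out of every list. Lists were tested on log2 CPM with camera of limma 3.58.1 at a preset correlation of 0.01, and as alternatives with a correlation estimated per list and with fry, which asks whether the genes of a list move in 1 direction on balance and does not compare them with other genes. Means of a list per library were also compared between groups with exact two-sided permutation tests and, over the 6 same-numbered pairs, with exact two-sided sign-flip tests.

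The text names genes by a rule fixed before the data were examined: Psmb5 and Psmb8; per comparison the 8 called genes with the largest rise and the 8 with the largest fall among those at a mean of 1 CPM or more and with a proper symbol; and per list up to 3 called members or, where none was called, the member with the smallest p. Since no gene other than Psmb5 and Psmb8 was called without the block, the rule was applied to the blocked fit as well, a choice made after the data were seen. Further list members that passed the threshold over the list alone are given as examples, also chosen after their values were seen. Some genes of the lists are not reported here by name.

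Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors, library sizes without Psmb5 and Psmb8, no low-count filter, a minimum of 5 CPM, fits of only the groups compared, the replicate block, a fold threshold of 0.3 on the log2 scale, counts thinned to the smallest library, and each library left out. Alternatives within the blocked fit, removal of a GC or length trend per library among them, were added after the data were seen. The tests were tested on simulated data, drawn from the library sizes of the real counts and the means and dispersions of the blocked fit. Differences between replicate numbers were kept the same in all groups, so a lead of the blocked test is in part built into these data. In the simulated Psmb8 against mSc comparison over 15546 genes, the unblocked test recovered 10.4%, 61.2% and 90.9% of genes changed by 0.25, 0.5 and 1 on the log2 scale with 0 false calls of 108, and the blocked test 56.7%, 83.6% and 98.5% with 14 false calls of 173. A simulated GC trend gave 1546 false calls before and 1 after its removal.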

Results

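Bulk RNA sequencing of poly(A)-enriched libraries measured gene transcripts in cultures of mouse cortical neurons. The cultures were transduced with lentivirus at 7 days in vitro and harvested after 10 further days. They fell into 3 groups of 6 libraries. The mSc group overexpressed mScarlet, a red fluorescent protein used as a control. The Psmb5 group overexpressed Psmb5, the catalytic β5 subunit of the constitutive 20S proteasome. The Psmb8 group overexpressed Psmb8, the β5i subunit that takes its place in the interferon-inducible immunoproteasome. Library totals ranged from 15337511 to 21074229 counts in mSc, from 16055974 to 19640543 in Psmb5 and from 16091906 to 18630396 in Psmb8. The labels do not say whether the replicates came from separate animals or dissections, so the p-values measure the spread between these libraries, which may be partly technical. A treatment text in the labels names an Ifng construct for all samples, against the 3 constructs in the treatment tags and the design text. Ifng, which lies outside the naming rule and was added after its values were seen, had 11 counts over the 18 libraries and at most 3 in any library.

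Libraries that shared a replicate number resembled each other across groups. Interferon-stimulated genes were high in the libraries numbered 3 and 6 of each group. The mean log2 CPM over the 30 tested members of that list was 3.11, 2.55 and 2.62 in replicate 3 of mSc, Psmb5 and Psmb8, and 4.11, 3.98 and 3.72 in replicate 6. The other 12 libraries lay between 0.45 and 1.65. Astrocyte markers, a list of 17 genes with Gfap and Aqp4 among them, stood at 7.95, 7.74 and 7.76 in replicate 1 of mSc, Psmb5 and Psmb8, and between 6.24 and 6.74 in the other 15 libraries. Of 15671 genes tested, 10078 differed between replicate numbers (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of 18 microglia markers, 3 were expressed well enough to be tested, Cd68 and Aif1 among them, so that list was not tested as a set.

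**Figure D1:**
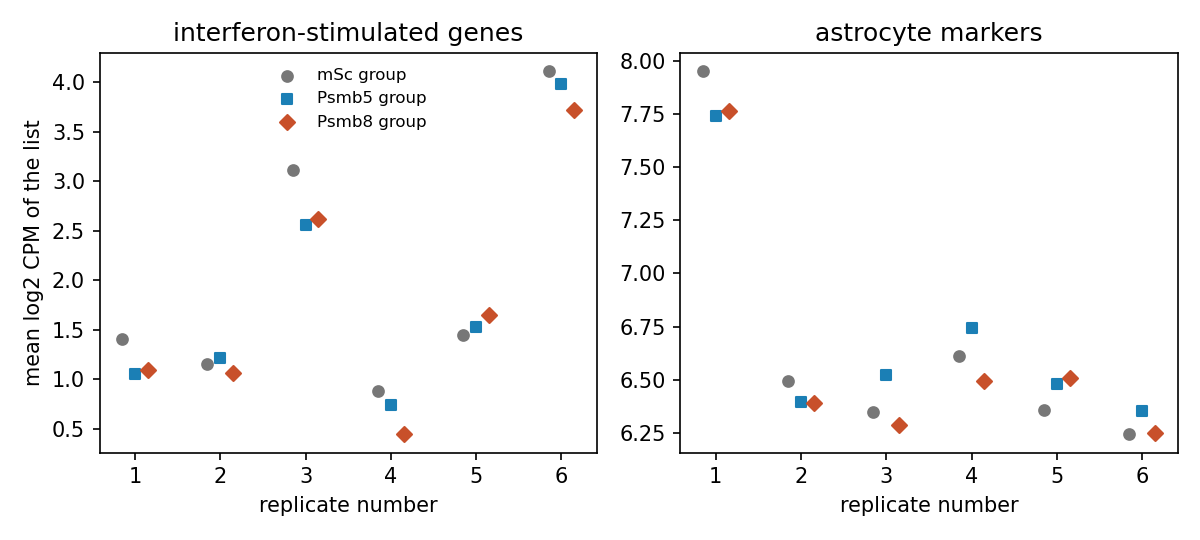
Mean log2 CPM of the interferon-stimulated genes (left) and of the astrocyte markers (right) in each library, against its replicate number; each point is 1 library and its shape and colour give the group. The interferon-stimulated genes stand at 2.55 or more in the libraries numbered 3 and 6 and at 1.65 or less in the others, and the astrocyte markers at 7.74 or more in the libraries numbered 1.

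The overexpressed transcripts were present in the groups the labels name. Psmb5 (ENSMUSG00000022193, chromosome 14, 54614119 to 54618022, minus strand, 3 exons in its principal transcript, GRCm38) stood at 42.9 ± 1.49 CPM in mSc, 451 ± 113 in Psmb5 and 48.3 ± 1.90 in Psmb8 cultures (SD, n = 6 each). Psmb8 (ENSMUSG00000024338, chromosome 17, 34197721 to 34201454, plus strand, 6 exons) stood at 6.28 ± 7.76 CPM in mSc, 5.03 ± 5.48 in Psmb5 and 887 ± 198 in Psmb8 cultures (SD, n = 6 each). Psmb5 was 10.5 times higher in Psmb5 than in mSc cultures, a log2 fold change of 3.39 (SE 0.14, adjusted p = 4.3e-11). Psmb8 was 141 times higher in Psmb8 than in mSc cultures, a log2 fold change of 7.12 (SE 0.77, adjusted p = 3.5e-04). The ratio of Psmb8 to Psmb5 transcript was 18.5 ± 4.55 in Psmb8 cultures and 0.144 ± 0.174 in mSc cultures. Endogenous Psmb8 in mSc ranged from 0.840 to 19.4 CPM, highest in replicates 6 and 3. Replicate 2 had the lowest transgene level in both overexpression groups, 238 CPM of Psmb5 and 546 CPM of Psmb8. Psmb5 was 1.12 times higher in Psmb8 than in mSc cultures, with no overlap between the 6 libraries of each (exact two-sided permutation p = 0.0022, the smallest that 6 against 6 can give). In edgeR the same difference was 0.17 on the log2 scale (SE 0.13) and was not called (adjusted p = 0.655 with the replicate number as a block). That fit estimates 1 dispersion per gene from all 3 groups, so the spread of the Psmb5 group (SD 113 CPM) enters it. The miss therefore says little about mSc and Psmb8 cultures, where the SDs were 1.49 and 1.90.

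**Figure D2:**
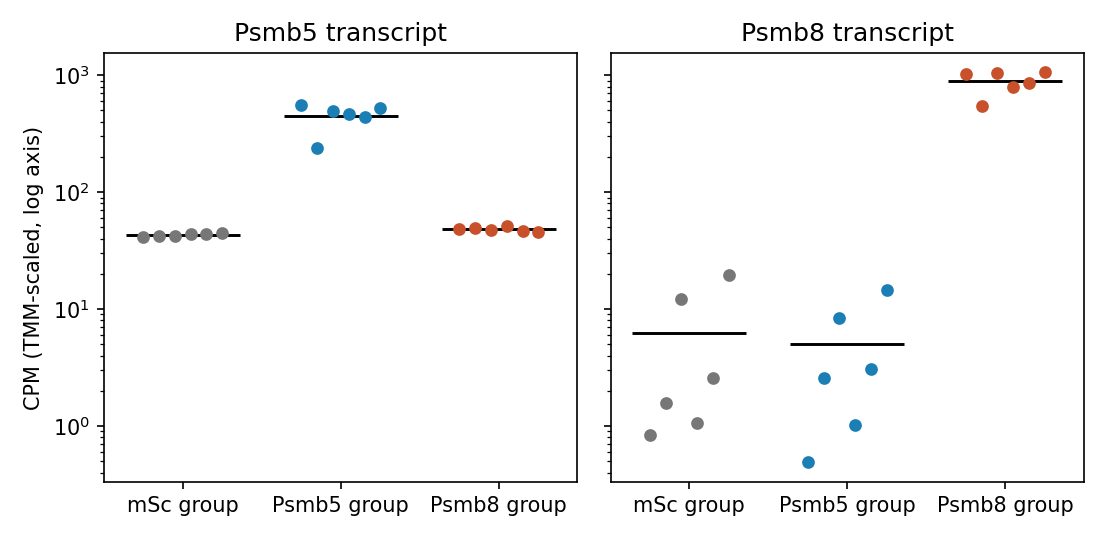
Psmb5 (left) and Psmb8 (right) transcript in each library, in TMM-scaled CPM on a log axis; each point is 1 library, the horizontal bars are group means. Psmb5 lies at 238 CPM or more in the Psmb5 group and at 51.1 or less elsewhere, and Psmb8 at 546 or more in the Psmb8 group and at 19.4 or less elsewhere.

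The comparison of Psmb5 with mSc cultures asked what more of the constitutive catalytic subunit does to the neuronal transcriptome. Psmb5 itself rose, and no other gene of 15671 passed the threshold, either without or with the replicate number as a block. The other proteasome subunits lay close to mSc: the 32 subunits of the 20S core and the 19S regulatory particle were on average 0.02 ± 0.03 higher on the log2 scale (SD over 6 same-numbered pairs; 4 of 6 pairs higher; exact sign-flip p = 0.25). An unadjusted p under 0.05 was reached by 148 genes without the block and by 1077 with it, where chance alone gives 784. With the block DESeq2 called 13 genes, limma-voom 1 and edgeR without a low-count filter 140.

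Among the fixed gene lists, none of the 26 tested was called in Psmb5 against mSc without the block (limma's camera), and 7 were called with it. Cholesterol biosynthesis had the smallest adjusted p of these (1.0e-06). In this list 22 of 22 members lay above mSc, with a median log2 fold change of 0.13 and none passing on its own. Its members vary together (estimated correlation 0.71), so they do not count as 22 separate results. The list mean was higher in 5 of 6 pairs (0.15 ± 0.15, SD; exact sign-flip p = 0.0625, 0.474 adjusted over 26 lists). Activity-regulated immediate early genes were also called upward (adjusted p = 0.0036), and 3 of 25 rose when adjusted over the list alone: Nr4a3, a nuclear receptor, by 0.22 (SE 0.05), Dusp4 by 0.18 (SE 0.05) and Inhba, an activin subunit, by 0.52 (SE 0.16). Heat shock genes (adjusted p = 0.029) and the integrated stress and unfolded protein response (adjusted p = 0.046) were called upward with no member passing. Interferon-stimulated genes were called downward (adjusted p = 0.0012), with Gbp2 alone of 30 passing over the list (log2 fold change -0.52, SE 0.14, lower in 4 of 6 pairs; -0.29 without replicate 3). Immunoproteasome and MHC class I genes were called downward (adjusted p = 0.0066) with no member of 14 passing. Mitochondrially encoded transcripts were called downward (adjusted p = 0.0042), and 3 of 13 fell over the list alone: mt-Co3 by 0.34, mt-Co2 by 0.28 and mt-Nd3 by 0.19. Each of the 7 calls was lost with an estimated correlation (adjusted p = 0.74), and fry called none. The other 19 lists, oxidative phosphorylation, glycolysis, the pentose phosphate pathway, NRF2 targets, ferroptosis, autophagy, ribosomal proteins, p53 targets, NF-kB response, the 3 proteasome lists, synapse and the 6 other cell type and cycling lists, had medians between -0.05 and 0.17. Without the block, leaving out mSc replicates 1, 2, 3, 4 or 6 gave 3, 1, 6, 11 and 7 called lists, and leaving out Psmb5 replicates 1, 2, 5 or 6 gave 5, 2, 5 and 3. With the block, leaving out replicate 6 gave 11 lists and 3 genes. Of the 7 blocked calls only cholesterol held with each replicate left out. The interferon and MHC lists were lost without replicate 3 (adjusted p = 0.13 and 0.069), immediate early genes without 5 (0.058) and mitochondrial transcripts without 2 or 4 (0.072 and 0.11). The same held for heat shock without 1 or 3 (0.36 and 0.13) and the integrated stress response without 1, 2 or 4 (0.47, 0.072 and 0.25). The heat shock median was 0.017 and 0.033 in these runs, against 0.026 with all replicates. That of the integrated stress response was 0.014, 0.042 and 0.029, against 0.023.

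The comparison of Psmb8 with mSc cultures asked what the immunoproteasome subunit does to neurons that do not otherwise make much of it. Transcripts of the whole 26S proteasome were slightly higher in Psmb8 cultures. The 13 other subunits of the 20S core were on average 9.25% higher, and the 19 subunits of the 19S regulatory particle, which recognises and unfolds ubiquitinated substrates, 9.45% higher. On the log2 scale these were 0.13 ± 0.06 and 0.13 ± 0.05 (SD over 6 same-numbered pairs), higher in 6 of 6 pairs in both lists. With the replicate block, 11 of 13 core subunits and 16 of 19 regulatory subunits rose when adjusted over the list alone, and 0 and 1 over all genes; without it 4 and 8 rose over the list alone, and none over all genes. The regulatory ATPase Psmc5 rose by 0.20 (SE 0.04, adjusted p = 0.033 over all genes). Psmb2, a core β subunit, rose over its list alone by 0.19 (SE 0.04), and so did the ATPase Psmc2 by 0.18 (SE 0.04), Psmb3 by 0.17 (SE 0.04) and the lid subunit Psmd11 by 0.16 (SE 0.04).

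Camera called both proteasome lists without the block (adjusted p = 3.3e-15 for the core and 9.5e-21 for the regulatory particle). Both calls were lost with an estimated correlation (adjusted p = 0.070 for each without the block, and 0.087 and 0.076 with it). The rotation test fry called both with the block (adjusted p = 0.0034 and 0.0014) and neither without it (adjusted p = 0.069 for each). Regrouping the 12 libraries at random gave as many called lists in 80 of 100 splits, and swapping labels within pairs in 5 of 32, so the number of called lists does not set this grouping apart. An exact permutation test of the list means between 6 and 6 libraries, which ignores the pairs, gave p = 0.0087 for the core and 0.011 for the regulatory particle. These values were not adjusted over the 26 lists. The exact sign-flip test over 6 pairs gave the smallest p it allows, 0.031, or 0.203 after adjustment over 26 lists. In all, 4 lists reached this p, those of oxidative phosphorylation and heat shock among them. Assembly factors and other activators were called without the block (adjusted p = 0.019; 0.75 with an estimated correlation), with none of 17 passing. With the block that call was lost without replicate 2 or 4 (adjusted p = 0.051 and 0.26). Pomp, a chaperone of core assembly, was at 0.14 (SE 0.04, adjusted p = 0.21 with the block).

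**Figure D3:**
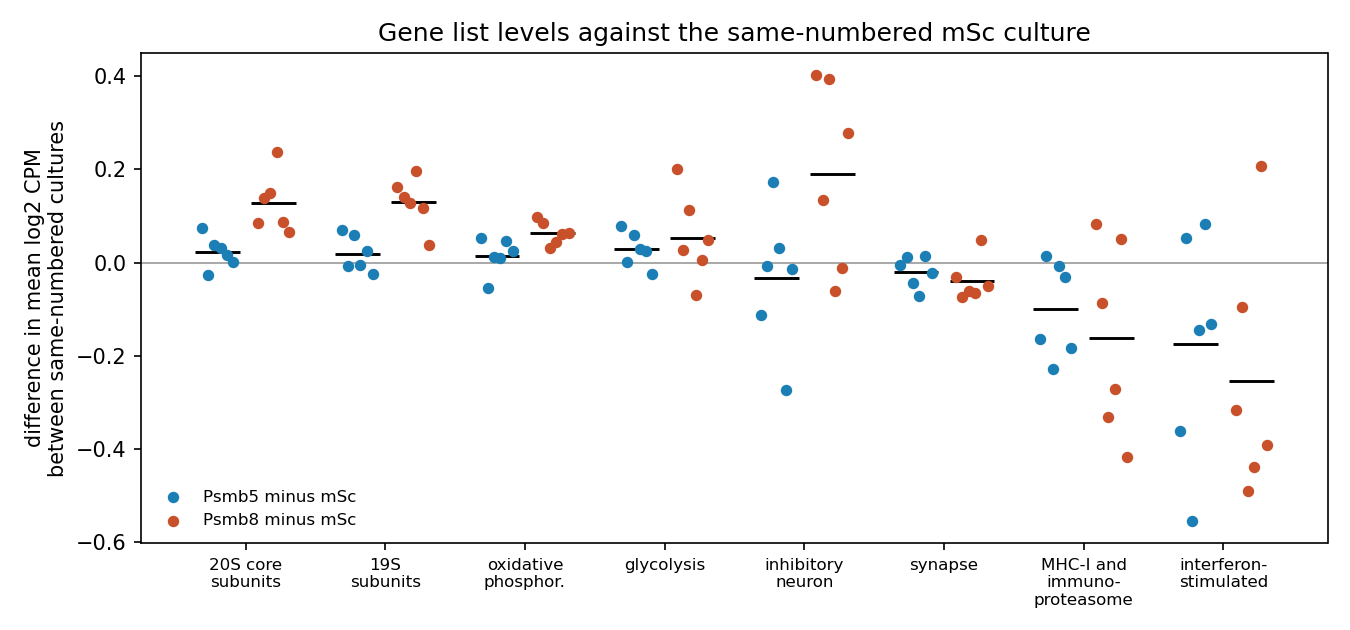
Difference in the mean log2 CPM of 8 gene lists between same-numbered libraries, Psmb5 minus mSc and Psmb8 minus mSc; each point is 1 pair and the bars are means over 6 pairs. The 20S, 19S and oxidative phosphorylation lists are above 0 in 6 of 6 pairs for Psmb8, with means of 0.13, 0.13 and 0.06.

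Lists of metabolic genes were called in both directions in Psmb8 against mSc cultures, with small differences and no member passing over all genes. Nuclear-encoded oxidative phosphorylation genes were 4.53% higher on average (0.06 ± 0.02 on the log2 scale, SD, 6 of 6 pairs; exact sign-flip p = 0.031, 0.203 adjusted over 26 lists), and with the block 4 of 33 rose over the list alone, cytochrome c (Cycs) by 0.25 (SE 0.06) and the complex I subunit Ndufa1 by 0.18 (SE 0.06) among them. With the block 8 of 23 glycolysis genes rose over the list alone, among them enolase 1 (Eno1) by 0.14 (SE 0.04), Tpi1 by 0.13 (SE 0.04), Gapdh by 0.13 (SE 0.03) and Aldoa by 0.12 (SE 0.03); the list mean was higher in 5 of 6 pairs (exact sign-flip p = 0.219). Taldo1 of the pentose phosphate pathway rose by 0.15 (SE 0.04), 1 of 11 over its list, and so did 2 of 22 cholesterol genes, Hsd17b7 by 0.28 (SE 0.09) and Sc5d by 0.19 (SE 0.05). The cholesterol mean was higher in 3 of 6 pairs (0.14 ± 0.31, SD; exact sign-flip p = 0.438) and without replicate 4 the mean difference was 0.026. Heat shock genes and chaperones were called upward with none of 25 passing, and Cacybp stood at 0.14 (SE 0.04). Their mean was 2.50% higher, in 6 of 6 pairs (exact sign-flip p = 0.031, 0.203 adjusted over 26 lists). The 13 mitochondrially encoded transcripts were all below mSc with the block, with none passing, and mt-Nd3 was at -0.15 (SE 0.05). Their mean was lower in 4 of 6 pairs (-0.10 ± 0.17, SD, exact sign-flip p = 0.219). Camera called oxidative phosphorylation (adjusted p = 8.3e-08), glycolysis (0.019) and heat shock (0.011) without the block, and with it also the pentose phosphate pathway (0.019), cholesterol (2.6e-05) and, downward, the mitochondrially encoded transcripts (0.0090). With an estimated correlation the adjusted p without the block was 0.72 for oxidative phosphorylation, 0.75 for glycolysis and 0.75 for heat shock, and in the blocked fit it was 0.20 for oxidative phosphorylation, 0.20 for glycolysis, 0.35 for heat shock, 0.30 for the pentose phosphate pathway, 0.44 for cholesterol and 0.42 for the mitochondrial transcripts. Fry with the block called oxidative phosphorylation (adjusted p = 0.024) and glycolysis (adjusted p = 0.027) of these. With the block camera did not call cholesterol without replicate 4 (adjusted p = 0.38), the pentose phosphate pathway without 2 or 4 (0.055 and 0.27) or the mitochondrial transcripts without 2, 3 or 4 (0.086, 0.088 and 0.14). The medians in these runs were 0.014 for cholesterol (0.145 with all replicates) and 0.063 and 0.029 for the pentose phosphate pathway (0.063). For the mitochondrial transcripts they were -0.041, -0.029 and -0.055 (-0.063). NRF2 targets and glutathione enzymes, the ferroptosis list, the integrated stress and unfolded protein response and p53 targets were not called in either fit. Gsr, glutathione reductase, was at 0.14 (SE 0.05, adjusted p = 0.30), Vdac3 at 0.13 (SE 0.04, adjusted p = 0.20) and Hrk, a pro-apoptotic BH3 protein, at -0.21 (SE 0.06, adjusted p = 0.12).

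In the synapse list some genes fell in Psmb8 against mSc cultures, and in the list of inhibitory neuron markers some rose. Grin1, the obligatory subunit of NMDA receptors, fell by 0.33 (SE 0.05, adjusted p = 0.0060 with the block) and the postsynaptic scaffold Shank3 by 0.27 (SE 0.04, adjusted p = 0.0039), both in 6 of 6 pairs. Over the list alone 4 of 32 synapse genes fell, Camk2a by 0.16 (SE 0.04) among them, while 13 of 32 lay above 0. Of 14 inhibitory neuron markers 7 rose over the list alone with the block, among them the neuropeptides Vip by 0.44 (SE 0.10), Sst by 0.40 (SE 0.11) and Npy by 0.38 (SE 0.13) and the GABA-synthesising enzymes Gad1 by 0.15 (SE 0.05) and Gad2 by 0.13 (SE 0.04). The mean of the inhibitory list was higher in 4 of 6 pairs (0.19 ± 0.20, SD; exact sign-flip p = 0.125). Of 14 excitatory neuron markers 2 fell over the list alone, Cux2 and Nrgn by 0.18 each, and the list was not called. Camera called the inhibitory list without the block (adjusted p = 0.011; 0.75 with an estimated correlation) and with it (7.3e-05; 0.30 with an estimated correlation), and synapse only with the block (adjusted p = 0.019; 0.42 with an estimated correlation). The blocked synapse call of camera was lost without replicate 2, without 4 and without both 3 and 6 (adjusted p = 0.091, 0.10 and 0.097). Its median was -0.010, -0.013 and -0.014 there, against -0.021 with all replicates. The inhibitory call was lost without both 3 and 6 (0.053), with a median of 0.13 against 0.14. Astrocyte, oligodendrocyte, vascular and cycling lists were not called; their medians were -0.07, -0.11, 0.03 and 0.01.

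Some interferon-stimulated genes were lower in Psmb8 than in mSc cultures once same-numbered libraries were compared. Gbp2, an interferon-induced GTPase, fell by 0.86 (SE 0.14, adjusted p = 0.0060 with the block). Over the list alone 9 of 30 interferon-stimulated genes fell with the block, Gbp3 by 0.54 (SE 0.13), Bst2 by 0.52 (SE 0.16) and Iigp1 by 0.76 (SE 0.25) among them. So did 8 of 14 immunoproteasome and MHC class I genes, the β1i subunit Psmb9 by 0.60 (SE 0.14), H2-K1 by 0.29 (SE 0.10) and B2m by 0.20 (SE 0.07) among them. The interferon list was lower in 5 of 6 pairs (-0.25 ± 0.27, SD; exact sign-flip p = 0.094) and the MHC list in 4 of 6 (-0.16 ± 0.21, SD; p = 0.156). Camera called both lists with the block (adjusted p = 2.9e-06 and 5.7e-05; 0.25 and 0.30 with an estimated correlation) and neither without it (0.076 and 0.23). Without the libraries numbered 3 and 6, in which these genes are high, the interferon list had a median of -0.13 and was not called (adjusted p = 0.183), and neither was the MHC list, with a median of -0.04 (adjusted p = 0.43). The NF-kB response was not called; Vcam1 was at -0.22 (SE 0.08).

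At the level of single genes, Psmb8 was the only call in Psmb8 against mSc without the block, and 51 genes were called with it, 18 higher and 33 lower. Besides Grin1, Shank3 and Gbp2, the genes that fell included Lsm11, a component of the U7 particle that processes histone mRNA, by 0.43 (SE 0.04, adjusted p = 1.3e-05) and the postsynaptic protein dendrin (Ddn) by 0.38 (SE 0.06, adjusted p = 0.0039). The ubiquitin ligase Neurl1a fell by 0.36 (SE 0.05, adjusted p = 0.0024), Gp1bb by 0.46 (SE 0.07, adjusted p = 0.0039), Lrrc26 by 0.56 (SE 0.10, adjusted p = 0.016), Lamp5 by 0.35 (SE 0.07, adjusted p = 0.032) and lipoprotein lipase (Lpl) by 0.41 (SE 0.09, adjusted p = 0.046). Those that rose included the corticotropin-releasing hormone binding protein Crhbp by 0.65 (SE 0.14), the glucocorticoid-activating enzyme Hsd11b1 by 0.60 (SE 0.13) and Fam163a by 0.59 (SE 0.13). Also higher were the C-type natriuretic peptide precursor Nppc by 0.55 (SE 0.11), the growth factor Gdf10 by 0.54 (SE 0.09), Them6 by 0.38 (SE 0.08), neuronatin (Nnat) by 0.28 (SE 0.05) and Tmem35a by 0.27 (SE 0.05). The adjusted p values of these 8 genes lay between 0.0086 for Gdf10 and 0.048 for Hsd11b1, and all but Crhbp and Nppc (5 of 6 pairs) were higher in 6 of 6 pairs. In CPM, Ddn was at 817 ± 111 in Psmb8 and 1057 ± 65.0 in mSc cultures, Grin1 at 676 ± 91.7 and 852 ± 119, and Lsm11 at 81.4 ± 10.7 and 109 ± 11.8 (SD, n = 6). An unadjusted p under 0.05 was reached by 340 genes without the block and by 1675 with it, where chance alone gives 784. The blocked count was 19 without replicate 2, 9 without replicate 3, 19 without replicate 6 and 2 without both 3 and 6. It was 138 in DESeq2, 321 with no low-count filter and 24 with the Psmb5 libraries left out. In each of these the sign was kept by at least 50 of the 51 genes. The runs reuse libraries on which the genes were picked, so a kept sign says little. Of the 51 calls, 19 were kept without replicate 2, 9 without 3, 18 without 6 and 2 without both 3 and 6.

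**Figure D4:**
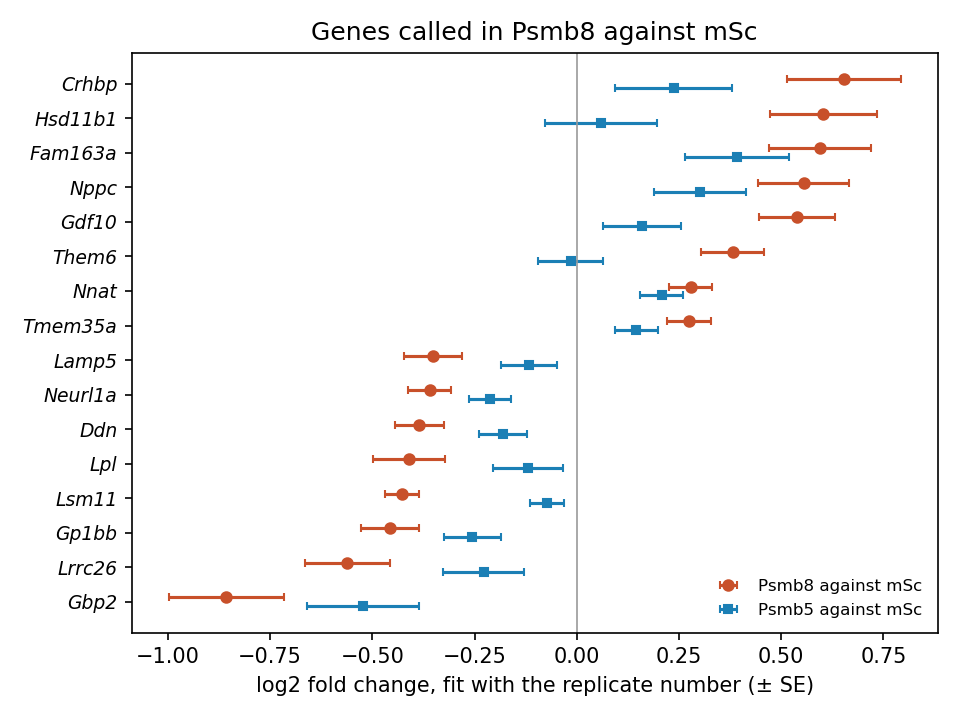
Log2 fold changes (± SE, 6 libraries per group) with the replicate number as a block, for the 8 genes with the largest rise and the 8 with the largest fall among those called in Psmb8 against mSc, with Psmb8 itself, genes under a mean of 1 CPM and genes without a proper symbol left out; circles are Psmb8 against mSc, squares Psmb5 against mSc. Of the genes shown, Gbp2 fell most, by 0.86, and Crhbp rose most, by 0.65.

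The direct comparison of Psmb8 with Psmb5 cultures asked which differences belong to the immunoproteasome subunit and not to overexpression of any β5 subunit. It uses the same 6 Psmb8 libraries as the comparison with mSc, so a result found in both is not found independently. The transgenes also differed in level, with 451 CPM of Psmb5 and 887 CPM of Psmb8 in their own groups. The proteasome subunits were again higher with Psmb8: the 20S and 19S subunits together by 0.11 ± 0.06 on the log2 scale (SD, 6 of 6 pairs; exact sign-flip p = 0.031, the smallest possible; 0.271 for each list after adjustment over 26 lists). With the block 8 of 13 core and 14 of 19 regulatory subunits rose over the list alone, Psmc4 by 0.17 (SE 0.03) and Psma5 by 0.16 (SE 0.04) among them, and 0 over all genes; without it 0 and 6 rose over the list alone. Of 14 inhibitory neuron markers 7 rose over the list alone with the block, Sst by 0.50 (SE 0.11) and Npy by 0.50 (SE 0.13) among them, and none over all genes. The list mean was higher in 5 of 6 pairs (exact sign-flip p = 0.0625, 0.406 adjusted over 26 lists; adjusted p = 0.27 with an estimated correlation). The activin subunit Inhba was lower by 0.73 (SE 0.16) and the astrocyte marker Gfap by 0.35 (SE 0.09), each the only member of its list to pass over the list alone. Besides Psmb5 and Psmb8, 4 genes were called with the block and none without it: Mgst3, a glutathione transferase of the microsomal family, rose by 0.25 (SE 0.04, adjusted p = 0.0075), and Lsm11 fell by 0.35 (SE 0.04, adjusted p = 2.2e-04), podoplanin (Pdpn) by 0.36 (SE 0.06, adjusted p = 0.0088) and the mitochondrial glutamate carrier Slc25a22 by 0.21 (SE 0.04, adjusted p = 0.026).

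Camera called 5 lists in Psmb8 against Psmb5 without the block: the core subunits (adjusted p = 3.6e-12), the regulatory particle (2.7e-19), oxidative phosphorylation (5.0e-06) and inhibitory neuron markers (1.6e-04) upward and the NF-kB response (0.0028) downward. With the block it called 8, adding glycolysis upward (0.0094), with Gpi1 at 0.13 (SE 0.03), and astrocyte markers (0.0021) and immediate early genes (0.024) downward. All were lost with an estimated correlation (adjusted p = 0.12 for the core and the regulatory particle and 0.72 for the rest without the block; 0.13 and 0.088 and then 0.27 or more with it), and fry with the block called the core and the regulatory particle alone (adjusted p = 0.017 and 0.0043). The NF-kB mean was lower in 3 pairs and higher in 3 (-0.19 ± 0.28, SD, exact sign-flip p = 0.25). With the block, the NF-kB call of camera was lost without replicate 4 (adjusted p = 0.062) and glycolysis without 1, 2 or 6 (0.12, 0.052 and 0.058). So were immediate early genes without 1 or 3 (0.38 and 0.29) and astrocyte markers without 3 (0.081). Interferon-stimulated genes were not called in this comparison (median -0.08; adjusted p = 0.127 with the block), nor was cholesterol biosynthesis (median 0.00; adjusted p = 0.95). The other lists not called had medians between -0.10 and 0.03. An unadjusted p under 0.05 was reached by 209 genes without the block and 1197 with it. Without replicate 4 the blocked count was 20 genes, and with the block it was 26 in DESeq2, 166 with no low-count filter, 16 with the mSc libraries left out and 11 with a GC trend removed. Without the block, leaving out Psmb5 replicate 6, Psmb8 replicate 4 or Psmb8 replicate 6 gave 9, 10 and 8 lists.

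The comparisons of Psmb5 and of Psmb8 with mSc were compared over their fold changes only, since Psmb5 itself is the only gene called in Psmb5 against mSc and no overlap of calls can be tested. Across 14320 genes, which are not independent replicates, the mean differences between same-numbered libraries correlated with r = 0.502 between the comparisons. Unchanged groups simulated against the same mSc libraries, with the differences between replicate numbers kept as in the blocked fit, gave a mean of 0.498 and at most 0.520 in 20 simulations. The covariance was 0.00617 against a simulated mean of 0.00499 and at most 0.00528. Each gene was simulated on its own, while real genes can vary together, so the simulated ranges are likely too narrow. A covariance above them is therefore no sign of a response that both groups share. The replicate numbers were also split 3 and 3 between the comparisons, so that each used 3 pairs and no mSc library was shared. There r was 0.022 on average over 20 splits, from -0.06 to 0.113, and the covariance 0.00051. With 3 pairs in each comparison this r is noisier than that over all pairs, so 0.022 and 0.502 cannot be compared directly. Noise in single comparisons lowers r but not the expected covariance, which was 0.00617 over all pairs and 0.00051 in the splits. Most of the covariance therefore came with the shared mSc libraries, and r = 0.502 is about what unchanged groups gave (mean 0.498).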

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

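In 21 of the 144 groups of 6 values examined (named genes and list means, per group), 1 library lay further from the other 5 than Dixon's test allows; chance gives about 1 in 20, or 7.2 groups here. Many of them are libraries numbered 1, 4 or 6. Gbp2 stood at 182, 136 and 94.5 CPM in replicate 6 of mSc, Psmb5 and Psmb8, with the next library of the group at 50.4, 23.0 and 23.5. The mean log2 CPM of the astrocyte markers was 7.95, 7.74 and 7.76 in replicate 1 of the 3 groups, with the next library at 6.61, 6.74 and 6.51. In replicate 1 of mSc the NF-kB list was low at 2.28 (next 3.24) and the p53 list low at 4.998 (next 5.27). In replicate 4 the pentose phosphate list was high in all 3 groups, 5.001 in mSc, 5.16 in Psmb5 and 5.21 in Psmb8 (next 4.85, 4.91 and 4.91), the NRF2 and glutathione list was high in Psmb5 at 6.86 (next 6.45) and in Psmb8 at 6.89 (next 6.34), and glycolysis was high in mSc at 7.29 (next 7.11). The 20S list was high in replicate 4 of Psmb8 at 6.26 (next 6.08), where Ddn was low at 605 CPM (next 814), and Pdpn was high in replicate 4 of Psmb5 at 80.7 CPM (next 45.1). Fam163a was high in replicate 1 of Psmb5 at 7.97 CPM (next 4.98), Hsd11b1 in replicate 1 of Psmb8 at 7.53 CPM (next 5.62), Gdf10 in replicate 5 of Psmb8 at 20.5 CPM (next 13.6) and Lsm11 in replicate 5 of mSc at 131 CPM (next 110).

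In the weighing that follows, the tests of neuron share and of transgene reads were chosen only after the result was seen. No prediction was written for the mean of the 32 subunits over regroupings and swaps, and the other tests were written down before their values were. An SE beside a median is the SD over the genes of a set divided by the root of their number. It treats the genes as independent, though genes of a list can vary together, so it understates the uncertainty between cultures. The higher proteasome transcripts of Psmb8 cultures could come from a GC bias between libraries, but removing the GC trend left the median log2 fold change of 32 subunits at 0.14 (SE 0.01; 0.13 before), and 32 of 32 above 0. They could come from subunits that vary together between cultures by chance, which the exact sign-flip test over 6 pairs speaks against only as far as its smallest p (0.031; 0.203 after adjustment over 26 lists). Reads of the Psmb8 transgene counted to related core subunits would not raise the unrelated 19S subunits, whose median was 0.13 (SE 0.01) against 0.12 (SE 0.01) for the core. An effect of the Psmb8 transgene stays open, beside virus dose, which was not tested, and a shift in cell composition. Such a shift stays open since 7 of 14 inhibitory neuron markers rose as well (list mean 0.19 higher). The mean over the 32 subunits was 0.129 in the real grouping and at most 0.114 in 99 random regroupings of the 12 libraries. Over the 31 other ways to swap labels within pairs it was at most 0.113. With 6 of 6 pairs higher no swap could give a larger mean, so the swaps only repeat the sign-flip test. The rise was also present against Psmb5 cultures, which carry a transgene as mSc cultures do. It was 0.109 there, with 0.111 the highest of 99 regroupings and 0.0889 the highest of 31 swaps. Here too 6 of 6 pairs were higher, so no swap could exceed the real mean. The same 6 Psmb8 libraries enter both comparisons, so this is not independent evidence. Psmb8 stood at 887 CPM in its group and Psmb5 at 451 in its own, so subunit and transgene level cannot be told apart.

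The 33 genes that fell in Psmb8 against mSc with the block, Grin1, Shank3, Ddn and Neurl1a among them, could reflect a GC bias, but their median was -0.25 (SE 0.04) with the GC trend removed and -0.29 (SE 0.04) before. A bias by gene length could do the same, and with the length trend removed the median was -0.28 (SE 0.04), below 0 for 33 of 33 either way. A lower share of neurons in the Psmb8 cultures could lower neuronal transcripts, but the 14 excitatory neuron markers had a median of -0.013 (SE 0.03), 7 above 0 and 7 below. Inhibitory neuron markers went the other way (7 of 14 rose over the list alone) and Cux2 and Nrgn fell by 0.18 each, so a shift between neuron types stays open beside an effect of Psmb8. These genes were picked for their fall, so their medians are larger than a new experiment would be likely to give.

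The lower interferon-stimulated genes of Psmb8 cultures could depend on the interferon background of the libraries numbered 3 and 6. In edgeR's blocked fit the median log2 fold change was -0.13 (SE 0.05, 27 genes) without these and -0.31 (SE 0.05, 30 genes) with them. From log2 CPM, which camera used, the medians were -0.13 and -0.22. How much of the fall is kept depends on the scale, which does not decide between the explanations. A chance difference between same-numbered cultures could also give it: the exact sign-flip p over 6 pairs was 0.094. With the block camera also called the list downward in Psmb5 against mSc (adjusted p = 0.0012), with a mean of -0.18 and lower values in 4 of 6 pairs. It did not call the list in Psmb8 against Psmb5 (adjusted p = 0.127). A difference that both comparisons with mSc share is therefore open as well. An effect of Psmb8 cannot be told from these explanations on 6 pairs.

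How often chance groupings give as many calls was tested by regrouping the libraries of a comparison, 100 splits without the block and all 32 label swaps within pairs with it, the real grouping counted in both. Without the block as many genes were called in 3 of 100 splits for Psmb5 against mSc (1 in the real grouping, highest other 6), 3 of 100 for Psmb8 against mSc (1, highest other 4) and 1 of 100 for Psmb8 against Psmb5 (2, highest other 0). These counts hold only Psmb5 and Psmb8, the overexpressed genes, so they say nothing about other genes. With the block the number was 9 of 32 for Psmb5 against mSc (1, highest other 1), where the gene is again Psmb5 and its 10.5-fold difference, not the count, sets the groups apart, and 1 of 32 for Psmb8 against mSc (51, of which 50 are not the transgene; highest other 15) and for Psmb8 against Psmb5 (6, of which 4 are not the transgenes; highest other 0), the smallest share 32 swaps can give, so chance can be excluded only to that limit. For called lists without the block the numbers were 100 of 100 for Psmb5 against mSc (0 in the real grouping, highest other 20), 80 of 100 for Psmb8 against mSc (7, highest other 19) and 91 of 100 for Psmb8 against Psmb5 (5, highest other 17), and with the block 13 of 32 (7, highest other 14), 5 of 32 (13, highest other 15) and 14 of 32 (8, highest other 12). For no count of lists can chance be excluded, so a camera call with the preset correlation is weak evidence by itself in these cultures. The unblocked splits with the most calls parted 4 of 6 pairs, and so mixed replicate numbers unevenly. Of the 8 drawn splits that part 6 pairs, the real one included, as many lists were called in 8, 3 and 3 for Psmb5 against mSc, Psmb8 against mSc and Psmb8 against Psmb5.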

How the results depend on the processing

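All alternatives within the blocked fit, and the runs without the libraries numbered 3 and 6, were chosen after the result was seen; the others were planned. Values of named genes under an alternative or without a library were measured against the fit without the block, in which only Psmb5 and Psmb8 are called. Of these values, 5739 kept direction and side of the threshold, 346 kept direction and newly passed it, 0 kept direction and no longer passed it, and 24 reversed. Psmb5 and Psmb8 were left out of this tally, so no call could be lost and the 0 was fixed in advance. For lists the numbers were 816, 232, 72 and 0. The 23 results of named genes called with the block, the transgenes apart, kept their direction in all alternatives within the blocked fit that gave a value, but kept the call in 255 of these values and lost it in 106, above all without replicates 3 and 6 (2 kept, 21 lost) and without replicate 3 (4 kept, 19 lost). These alternatives reuse libraries on which the genes were called, so a kept direction says little. The calls of Psmb5 and Psmb8 held in every alternative. The block changed no call beyond those counted here and in the report, which names only part of the genes. The cause of the changes below was not tested, except that fewer libraries or smaller residual variance change how many genes pass. Leaving 1 library out of the fit without the block also leaves its replicate number missing from 1 group, and 10078 of 15671 genes differed between replicate numbers. Genes called without the block: Psmb8 against mSc 1, but 2 in DESeq2 and 51 with the block (1 to 2 with a library left out; 2 without Psmb8 replicate 5); Psmb8 against Psmb5 2, but 4 in DESeq2 and 6 with the block. Genes called with the block: Psmb5 against mSc 1, but 13 in DESeq2, 140 with no low-count filter, 2 with only the groups compared, 2 without replicates 3 and 6 (1 to 3 with a replicate left out); Psmb8 against mSc 51, but 138 in DESeq2, 321 with no filter, 24 with only the groups compared and 2 without replicates 3 and 6 (9 to 59); Psmb8 against Psmb5 6, but 26 in DESeq2, 166 with no filter, 16 with only the groups compared and 11 with the GC trend removed (4 to 20). Lists called without the block: Psmb5 against mSc 0, but 7 with the block (0 to 11); Psmb8 against mSc 7, but 4 with no filter, 13 with the block, 0 with an estimated correlation and 0 in fry (5 to 13; 11 without mSc 1, mSc 3, Psmb8 1, Psmb8 5 or Psmb8 6); Psmb8 against Psmb5 5, but 8 with the block, 0 with an estimated correlation and 0 in fry (5 to 10). Lists called with the block: Psmb5 against mSc 7, but 0 with an estimated correlation and 0 in fry (5 to 11); Psmb8 against mSc 13, but 0 and 4; Psmb8 against Psmb5 8, but 5 without replicates 3 and 6, 0 with an estimated correlation and 2 in fry. Named genes turned direction only with 1 library left out of the fit without the block, where none of them is called, and for Myrf and Ccnb1 also with the block, where neither is called; Gbp2 in Psmb8 against mSc, called with the block, kept its direction there. They follow with the lowest and highest log2 fold change over the left-out libraries. Psmb5 against mSc: Irf1 -0.84 and 0.28, Ddx58 -0.45 and 0.054, Txnrd1 -0.014 and 0.32, Gbp2 -2.51 and 1.12, Taldo1 -0.031 and 0.20, Gsta4 -0.0087 and 0.29, Gfap -0.39 and 0.76, Myrf -0.23 and 0.74 (-0.098 with the block without replicate 4). Psmb8 against mSc: Psmb9 -1.55 and 0.28, Apoe -0.44 and 0.056, Ccnb1 -0.11 and 0.55 (-0.035 with the block without replicate 4), Gbp2 -2.57 and 0.70 (0.70 without mSc replicate 6), Ndrg2 -0.63 and 0.29, Rgs5 -0.16 and 1.27. Psmb8 against Psmb5: Psmb9 -1.23 and 0.67, Hmgcs1 -0.38 and 0.048, Gfap -0.87 and 0.14. With all libraries thinned to the smallest, 48 genes were called in Psmb8 against mSc with the block, 44 of them among the 51. What depth limits was tested in no other way; genes below the low-count filter were not tested.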

Other observations

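Genes called in Psmb8 against mSc with the block that the naming rule left out include the following, picked after their values were seen. The β-tubulins Tubb2b and Tubb4b rose by 0.27 (SE 0.05, adjusted p = 0.0083) and 0.20 (SE 0.04, adjusted p = 0.023), and Mgst3 by 0.24 (SE 0.04, adjusted p = 0.0057), as it did against Psmb5. Among those that fell were the GTPase-activating protein Arhgap33 by 0.31 (SE 0.04, adjusted p = 6.6e-04), the Arf6 exchange factor Psd by 0.29 (SE 0.05, adjusted p = 0.023), spinophilin (Ppp1r9b) by 0.26 (SE 0.06, adjusted p = 0.040) and Agap2 by 0.24 (SE 0.05, adjusted p = 0.023). The mitochondrial glutamate carrier Slc25a22 fell by 0.28 (SE 0.04, adjusted p = 6.6e-04), calsyntenin Clstn1 by 0.22 (SE 0.04, adjusted p = 0.016), the sodium-calcium exchanger Slc8a2 by 0.20 (SE 0.04, adjusted p = 0.039) and Wfs1, a protein of the endoplasmic reticulum, by 0.30 (SE 0.06, adjusted p = 0.023). No enrichment was tested among the called genes.

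Apart from the groups, the replicate numbers differed in lists other than interferon-stimulated genes and astrocyte markers. Cholesterol biosynthesis had a mean log2 CPM between 5.11 and 5.46 in replicates 2 and 5 of all groups and between 6.33 and 7.04 in the other 12 libraries, with the highest value in replicate 4 of Psmb8. Synapse genes lay between 8.40 and 8.54 in replicates 2 and 5 and between 8.64 and 8.76 in the others. Immediate early genes were between 6.58 and 6.94 in replicates 3 and 6, between 5.36 and 5.86 in replicates 2 and 5 and between 5.83 and 6.32 in replicates 1 and 4. Oligodendrocyte markers ranged from 2.47 to 3.37 in replicates 3 and 6 and from 3.73 to 5.28 in the others, and mitochondrially encoded transcripts from 7.28 to 7.58 in replicate 6 and from 7.64 to 8.31 in the others. The labels do not say what differs between the numbers.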
